A study of Mus musculus with 18 samples.

How the data were processed

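The series holds RNA-seq of 18 mouse liver samples, 3 at each of 6 time points (days 0, 7, 10, 14, 28 and 42) of infection with the blood fluke *Schistosoma japonicum*. Per the labels, the mice were infected through the skin with 40 ± 1 cercariae, the larvae that penetrate the skin, and the strain is written BLAB/c. Groups and replicate numbers were taken from the sample titles. The titles do not say that the 3 samples of a day came from separate animals, so the p-values measure the spread between these samples. No uninfected samples of the later days are among the samples, so time since infection and age of the animals change together.

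Per the submitters' processing notes, CASAVA, RSEM and the genome build mm10 were used, with no version given for either tool. RSEM assigns reads to transcripts by expectation maximisation, and reads that match several genes are divided among them. The authors deposited, for each sample, the RSEM expected count per gene cluster, with the transcript length, the effective length and the posterior standard deviation of the count, per the file headers. The library kit, read length, strand setting and read filters are not given in the sources used here. Each file lists 32732 gene clusters with 62996 transcript identifiers of the UCSC known gene kind, and 19719 of the clusters hold 1 transcript. At the 2 decimals the files give, between 6.7% and 11% of the expected counts of a library were not whole numbers, clusters at 0 included.

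The files number the clusters and do not pair them with gene names. None of the transcript identifiers (0 matches) was found in the gene name tables used here. No gene is therefore named, and 2 clusters higher and 2 lower at day 42 than at day 0 are given by number. The gene lists of immune, cell type, matrix and liver pathways that had been fixed before the data were examined, with their camera tests and the check of sex-linked genes, were not analysed here. Genes are described instead by abundance, transcript length and time profile, and these classes were chosen after the data were seen.

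Expected counts were rounded to whole numbers, because the test needs them. Of the 32732 clusters, 19967 had a count in any library and 13784 passed edgeR's filter on low counts (filterByExpr with its default settings on the 6 day groups). Libraries were scaled by TMM. edgeR's quasi-likelihood test (edgeR 4.0.16, R 4.3.3) was fitted to all 18 libraries with 1 coefficient per day, which leaves 12 residual degrees of freedom. The 5 infected days were each compared with day 0, and consecutive infected days with each other, 9 comparisons in all. A joint F-test of the day coefficients gave the genes changing over the time course. P-values were adjusted by the Benjamini-Hochberg method over the genes tested in each comparison, with 0.05 as the threshold. Log2 CPM for principal components used a prior count of 2. Standard errors of log2 fold changes were derived from the quasi-likelihood F statistic.

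The named clusters were those with the largest fold change between day 42 and day 0 among clusters past the threshold, with no overlap of the groups and a mean of at least 5 CPM in the higher group. That rule was written before the data were examined. The restriction to 2 in each direction follows from the missing names, and the part of the rule that leaves out immunoglobulin segments and gene models without a name could not be applied. Where a group had a count of 0, the fold was computed against a floor of 3 counts over the group's summed depth, and floors cover counting error only. The 10 abundant genes described by rank were those with the largest mean share of counts at any day, a choice made after the data were seen.

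Total expected counts per library ran from 15607108 to 37192367. Replicates of a day were compared by a chi-square of their counts per degree of freedom, which lay between 20.88 and 458.23, so no pair agreed within sampling noise and each library was counted as 1 sample. In all 18 libraries, 1644 clusters had values identical to those of another cluster, and 44 of them were among the tested. For 277 tested clusters the mean posterior standard deviation was above 10% of the mean count, which marks genes whose reads are shared with similar genes.

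The test was checked on simulated counts with 200 genes changed. In the simulation of day 42 against day 0, run on 13446 genes, edgeR recovered 87.9% of genes changed 4-fold, 54.5% of those changed 2-fold and 6.1% of those changed 1.5-fold. In the simulation of day 10 against day 7, run on 13459 genes, the shares were 87.9%, 52.3% and 14.1%. In that simulation 2.9% of edgeR's calls, 3.1% of limma-voom's and 9.8% of DESeq2's were false, and in the simulation of day 42 against day 0 the shares were 3%, 8.8% and 14.9%. Over the simulations of all 9 comparisons edgeR's share ran from 1.9% to 5.7%. Simulated genes varied independently of each other, with no deviation shared by many genes of a sample. The false shares, and their order between the tools, therefore need not hold for the real samples.

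The alternatives fixed before the data were examined were DESeq2 (1.42.0), limma-voom (limma 3.58.1), DESeq2 size factors, upper-quartile scaling, total counts without scaling, no filter on low counts, a stricter filter, the compared libraries alone, the replicate number as a block, an offset from the deposited effective lengths, a minimum of 2-fold, day 7 as the reference for days 28 and 42, and each library left out in turn. Those added after the data were seen removed each library's trend of log2 CPM with transcript length (a lowess curve with span 0.3), alone or with day 0 replicate 1 left out, or left out the 3 day 28 libraries.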

Results

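Liver RNA was sequenced at 6 time points of a *Schistosoma japonicum* infection in mice, with 3 liver samples at each of days 0, 7, 10, 14, 28 and 42. Adult worms of this fluke live in the veins that drain the gut, and their eggs lodge in the liver. Total expected counts were 37192367 for day 0 replicate 1, 27469473 for day 10 replicate 1, and 26368172 and 26028754 for day 42 replicates 1 and 3. The other libraries lay between 15607108 and 20804626. When every library was thinned to 15000000 counts, 16236 ± 94 genes (SD, n = 3) were detected at day 0, 15529 ± 51 at day 7, 15424 ± 132 at day 10, 15514 ± 56 at day 14, 15982 ± 126 at day 28 and 16652 ± 128 at day 42. The 3 infected days up to day 14 thus lay below the day 0 samples and day 42 above them by more than the spread of the replicates. Day 28 lay below them too, with 16102 in its highest sample against 16172 in the lowest of day 0. The 20 largest genes of a sample held 38.1% ± 4.5 of the counts at day 7 and 35.2% ± 1.8 at day 10. They held 27.5% ± 0.5 at day 0 and 27.7% to 29% on average at the later days. At equal depth a larger share leaves fewer counts for other genes.

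The first principal component held 42.9% of the variance and placed days 0 to 14 between -49.4 and -10.4, day 28 between 33.6 and 45.4, and day 42 between 72.6 and 103.8. The second held 16.5% and set day 0, at 42.8 to 70.6, apart from all infected samples, which reached at most 22.1. Rank correlations across genes between samples of the same day ran from 0.956 to 0.993, and between day 0 and day 42 from 0.872 to 0.93. Genes are not independent replicates in such correlations. The lowest value within a day belonged to day 42.

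**Figure D1:**
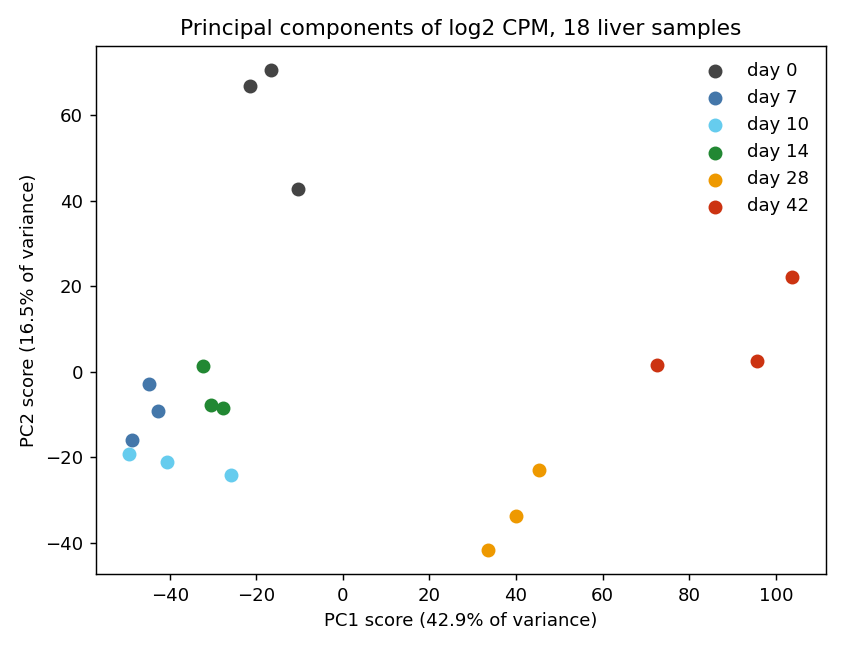
Scores of the 18 samples on the first principal component (horizontal, 42.9% of variance) and the second (vertical, 16.5%), each point 1 sample coloured by day. Days 28 and 42 lie to the right of all earlier samples, and the day 0 samples lie above the others at 42.8 to 70.6.

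The joint test asked which genes differed between any of the days. Of 13784 genes tested, 10857 (78.8%) changed over the time course at adjusted p under 0.05 (edgeR quasi-likelihood F-test), and 6196 of them spanned at least 2-fold between their highest and lowest day. The highest mean fell at day 42 for 3409 of the changing genes (31.4%), at day 28 for 2037 and at day 0 for 1794. Day 42 also held the lowest mean of 2777 genes (25.6%).

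**Figure D2:**
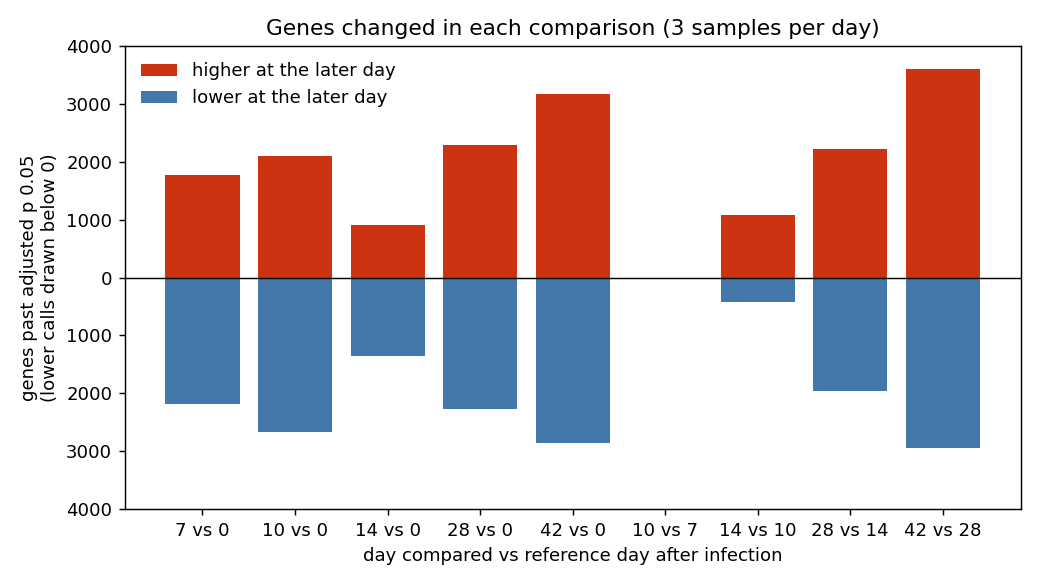
Number of genes past the adjusted p threshold in each comparison (horizontal axis), with genes higher at the later day drawn upward and genes lower at the later day drawn downward (vertical axis, number of genes). The count was 6014 at day 42 against day 0 and 6546 at day 42 against day 28, and no gene passed at day 10 against day 7.

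At day 7 against day 0 a single abundant gene rose from 1.14% ± 0.64 of all counts (SD, n = 3) to 12.8% ± 5.7, a log2 fold change of 3.88 (SE 0.66, adjusted p = 0.00062 by edgeR). It held 19.3% of the counts in day 7 replicate 1 and 8.78% and 10.3% in the other samples of that day. Another abundant gene rose from 0.439% ± 0.058 to 2.76% ± 0.32 of the counts, by 3 on the log2 scale (SE 0.45, adjusted p = 0.00023). Among the 100 most abundant genes 22 rose and 3 fell, but with total counts in place of TMM scaling 15 rose and 18 fell. Their joint share of the counts went from 44.4% ± 0.6 to 55.1% ± 3.3. With the leading gene taken out of both sides, they held 43.8% ± 0.6 of the remaining counts at day 0 and 48.5% ± 0.4 at day 7. In total 3941 genes changed, 1763 higher and 2178 lower, and of the 1408 that changed at least 2-fold 1038 were lower. Which direction held more genes depended on the processing. With total counts, 8% of the changed genes were higher in place of 44.7%, and the median of all genes moved from -0.07 to -0.42, while in 10 of 31 alternatives more genes were higher than lower. These were both other filters on low counts (52.8%), the compared libraries alone (53.5%), and the omission of day 0 replicate 1 (52.1%, or 1949 higher and 1948 lower when the length trend was also removed) or 3 (52.8%), day 14 replicate 2 (52.7%) or 3 (52.8%), day 28 replicate 3 (52.7%) or day 42 replicate 1 (53.2%). Among genes changed at least 2-fold the higher ones made up 26.3%, and 7.2% to 37.8% over the alternatives. Without day 7 replicate 3 the count was 2537.

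At day 10 against day 0 the leading gene held 9.41% ± 3.1 of the counts (log2 fold change 3.37, SE 0.65, adjusted p = 0.00097 by edgeR). Of the 100 most abundant genes 36 rose and 6 fell, or 26 and 11 with total counts. In all, 4773 genes changed, 2107 higher and 2666 lower, and 1372 of the lower ones fell at least 2-fold. Days 7 and 10 shared 3429 genes changed in the same direction, where independent lists would share 691. Simulations with no change and a shared day 0 group gave 0. Few genes pass at all without change, so this 0 is no measure of the overlap that shared samples create. The fold changes covaried across genes at 0.76 against 0.05 in the simulations, and part of the excess may come from the day 0 samples that both comparisons use. With total counts, 12.3% of the changed genes were higher in place of 44.1%, with a median of all genes of -0.36 in place of -0.06. More genes were higher than lower in 10 of 31 alternatives: with both other filters (53.8%), with the length trend removed (52.4%, or 52.3% when day 0 replicate 1 was also left out), and without day 0 replicate 1 (52.9%) or 3 (52.5%), day 14 replicate 2 (53.4%) or 3 (53.5%), day 28 replicate 3 (53.5%) or day 42 replicate 1 (53.8%). Of the genes changed at least 2-fold, 25% were higher, and 9.6% to 36.3% over the alternatives. Day 10 replicate 2 stood apart from the other samples of its day in some abundant genes: a gene at 0.161% and 0.19% of the counts in replicates 3 and 1 held 1.06% there.

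No gene passed the threshold between day 10 and day 7 by edgeR's quasi-likelihood test (smallest adjusted p 0.18). At unadjusted p under 0.05 there were 575 genes, fewer than the share of 0.05 of the 13784 tested that chance gives. DESeq2 called 13 genes and limma-voom 0. Leaving out day 0 replicate 3 or day 7 replicate 2 gave 1 gene each. The 2 groups did not overlap for 10.8% of genes, where chance gives 10%. In simulated data for this comparison 52.3% of genes changed 2-fold were recovered, so smaller changes were largely not detectable with 3 samples a day.

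By day 14 the leading gene had returned to 0.898% ± 0.083 of the counts and did not pass the test against day 0 (log2 fold change -0.19, SE 0.59, adjusted p = 0.86 by edgeR). The other abundant gene that rose at day 7 stayed high, at 3.24% ± 0.77 (log2 fold change 3.03, SE 0.45, adjusted p = 0.00041). Against day 0, 2264 genes changed, 916 higher and 1348 lower. With total counts 16% of them were higher in place of 40.5%, with a median of all genes of -0.17 in place of -0.03. The count was 1401 without day 14 replicate 1 and 1321 without day 14 replicate 2.

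Between day 10 and day 14, 1502 genes changed, 1086 higher and 416 lower. These changes ran against those of the first week. Of the genes changed at day 7 against day 0, 886 changed in the opposite direction between day 10 and day 14, where independent lists would share 225, and 9 in the same direction, where independent lists would share 205. The comparisons have no samples in common. The share of higher genes, 72.3%, was 93% with total counts (median of all genes 0.13 in place of -0.03) and 60% with a stricter filter on low counts. It was 56.4% with the trend on transcript length removed and 53.2% without day 0 replicate 1. That sample enters this comparison only through the filter on low counts, scaling and the shared spread. With the length trend removed the count was 2298. It was 946 without day 10 replicate 2 and 964 without day 14 replicate 3.

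**Figure D3:**
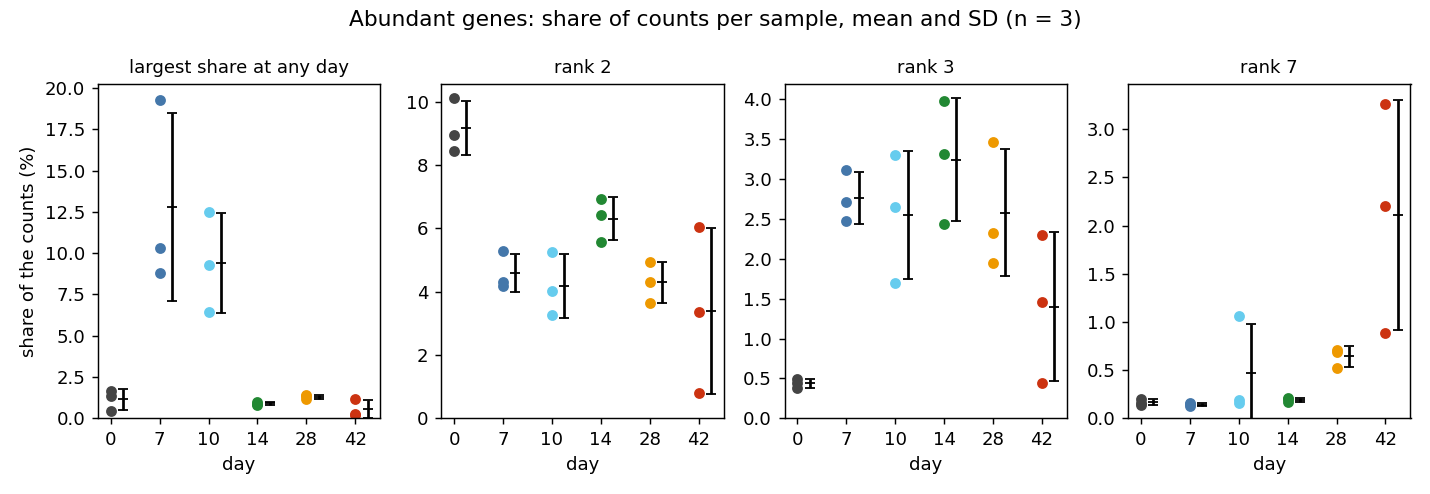
Share of all counts (vertical axis, percent, a separate scale for each panel) held by 4 abundant genes at each day (horizontal axis), with points for single samples and bars for mean and SD (n = 3). The gene on the left held 12.8% at day 7 and 0.898% at day 14, and the one on the right held 0.168% at day 0 and 2.11% at day 42.

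Day 28 opened a second phase of change. Cluster 6717 (transcript uc007pgo.1) had 0 counts at day 0 and 9.93 ± 7.58 CPM (SD, n = 3) at day 28, at least 255-fold higher, with an adjusted p of 0.00091 by edgeR's quasi-likelihood test. Without day 28 replicate 2 the mean was 5.56 CPM and the bound 144-fold, and without day 0 replicate 1 the bound was 125-fold. It lay at 0.0818 CPM or below, on average, at days 7, 10 and 14. Cluster 22788 (uc008zij.2) had 0 counts at day 0, 3.4 ± 0.305 CPM at day 7, 3.81 ± 0.868 at day 10, 4.14 ± 0.499 at day 14 and 22.9 ± 1.94 at day 28, and was at least 586-fold higher than at day 0 on day 28 (287-fold without day 0 replicate 1). It was absent at day 0 alone, so a difference of the day 0 mice other than infection stays open for its distance from day 0. The values at days 14 and 28 do not involve those mice. Against day 0, 4557 genes changed, 2285 higher and 2272 lower, and 2077 of them by at least 2-fold. The directions were near balance, with 50.1% higher and 38.3% (total counts) to 55.5% over 30 alternatives. More genes were lower in 6 of these, also with upper-quartile scaling (48.4%) and DESeq2 size factors (49.8%) and without day 42 replicate 2 (49%) or 3 (49.1%) or day 7 replicate 2 (2190 higher and 2191 lower). The balance joined opposed length classes. Of the 3447 genes with the shortest transcripts 859 were higher and 295 lower, and of the 3446 with the longest 280 were higher and 814 lower. Across genes the rank correlation of this fold change with transcript length was -0.3.

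Between day 14 and day 28, 4177 genes changed, 2227 higher and 1950 lower. The share of higher genes, 53.3%, fell below that of lower genes in 6 of 30 alternatives: without day 14 replicate 3 (47.3%), day 42 replicate 1 (49.2%), day 0 replicate 3 (49.6%) or day 0 replicate 1 (49.7%), with no filter (48.8%) and with the compared libraries alone (49.4%). Among genes changed at least 2-fold it was 71.6%, and 62.5% to 81.6% over the alternatives. The changes followed transcript length. Of the 3447 genes with the shortest transcripts, up to 1705 bases, 1067 rose and 77 fell, and of the 3446 with the longest, from 3923 bases, 198 rose and 1022 fell. The rank correlation across genes of the fold change with length was -0.47. Mean fragments, from the deposited effective lengths, were 182 to 192 bases at day 28, 195 to 196 at day 14 and 201 to 203 at day 42. With each library's length trend removed 3199 genes changed, and 2592 of them were among the 4177. The count was 2206 without day 28 replicate 1 and 2229 without day 14 replicate 2.

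**Figure D4:**
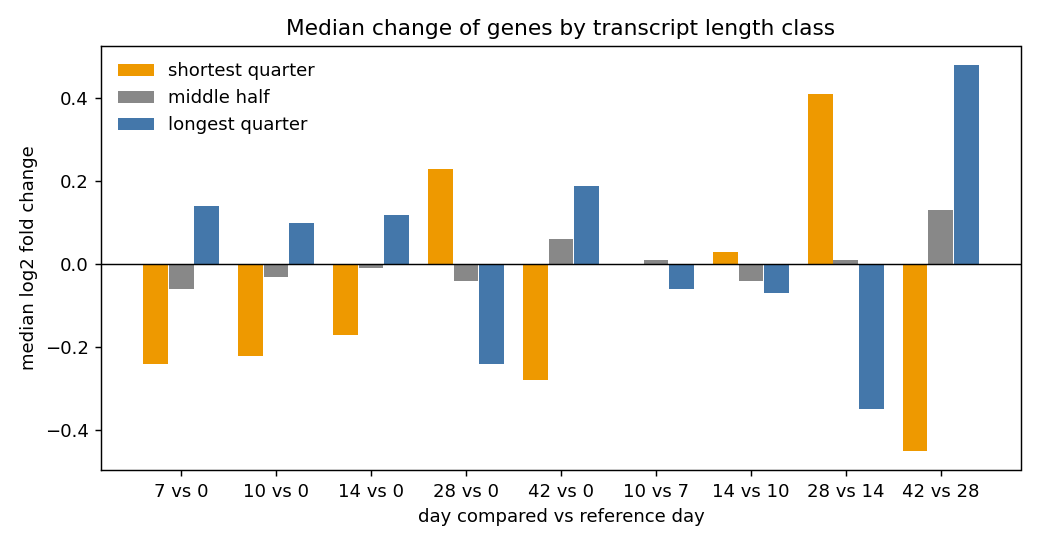
Median log2 fold change (vertical axis) of the 3447 genes with the shortest transcripts, the 3446 with the longest and the rest, in each comparison (horizontal axis). At day 28 against day 14 the medians are 0.41 for the shortest and -0.35 for the longest class, and at day 42 against day 28 they are -0.45 and 0.48.

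At day 42 cluster 6717 reached 196 ± 228 CPM, with single samples between 23.3 and 455, at least 5030-fold above day 0 (adjusted p = 6.7e-06 by edgeR). Without day 42 replicate 1 its mean was 67 CPM and the bound 1740-fold, and without day 0 replicate 1 the bound was 2460-fold. Cluster 22788 stood at 20.6 ± 6 CPM, at least 528-fold higher (adjusted p = 6.2e-10), or 258-fold without day 0 replicate 1. Cluster 25517 (uc012ezq.1) had 29.2 ± 8.45 CPM at day 0 and 0 counts at day 42, at least 810-fold lower (adjusted p = 9.7e-07, 521-fold without day 42 replicate 1 and 500-fold without day 42 replicate 3). Cluster 25516 (uc012ezp.1) had 16.4 ± 3.12 CPM and 0 counts, at least 454-fold lower (adjusted p = 2.3e-06, 292-fold and 280-fold without the same samples). Both were already at 0 to 3 counts over the 3 samples at each of days 7, 10, 14 and 28, and they belong to 4 clusters in a span of 6 numbers that were present at day 0 alone. For these clusters, and for the absence of cluster 22788 at day 0, a difference of the day 0 mice other than infection stays open. An abundant gene rose from 0.168% ± 0.032 of the counts at day 0 to 0.642% ± 0.11 at day 28 and 2.11% ± 1.2 at day 42 (log2 fold change 3.57, SE 0.6, adjusted p = 0.00016). The gene with the largest share at day 0 went from 9.15% ± 0.83 to 3.39% ± 2.6. It fell by 1.52 on the log2 scale (SE 0.45, adjusted p = 0.011), a call lost when the compared libraries alone were fitted (adjusted p = 0.12, with 0.00032 to 0.12 over 31 alternatives). Without day 42 replicate 2 its share was 2.07% and its log2 fold change -2.28, and over the alternatives the fold change ran from -2.28 to -1.13.

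In total 6014 genes changed at day 42 against day 0, 3164 higher and 2850 lower. Of those at least 2-fold changed, 1789 were higher and 951 lower, and higher genes made up 59% to 70.9% of these over the alternatives. Of all changed genes 52.6% were higher, and fewer were higher than lower in 11 of 31 alternatives: with DESeq2 size factors (3022 higher and 3025 lower), with the stricter filter (46.4%) or none (48.5%), with the length trend removed (47.9%, or 47.2% when day 0 replicate 1 was also left out), and without day 0 replicate 1 (46%) or 3 (45.8%), day 14 replicate 2 (46.4%) or 3 (46.5%), day 28 replicate 3 (46.4%) or day 42 replicate 1 (47.2%). More of the abundant genes fell than rose. Of the 900 genes that follow the 100 most abundant, 443 fell and 113 rose, and among the 100 most abundant 35 fell and 21 rose. At 2-fold or more 146 of the 900 fell and 59 rose, but among the 100 most abundant 17 fell and 18 rose. Of the genes higher at day 42, 960 passed at no earlier day against day 0, and 724 of these also rose between day 28 and day 42. Of the lower ones, 1301 passed at no earlier day, and 1076 of these also fell between day 28 and day 42. With the compared libraries alone in the fit, 3879 genes changed.

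Between day 28 and day 42, 6546 genes changed, with 3608 higher and 2938 lower. Among the 900 genes next to the most abundant 100, 502 fell and 58 rose. The length classes moved opposite to the step before: 338 of the shortest class rose and 1588 fell, and 1493 of the longest class rose and 137 fell. The rank correlation with length was 0.45 across genes, while against day 0 it was 0.22 at day 14 and 0.22 at day 42. Both steps use the same day 28 samples, so an excess of short transcripts in those samples alone would give opposite signs. With the length trend removed 5499 genes changed, of which 4182 were among the 6546. With total counts 72.9% of the changed genes were higher in place of 55.1%, with a median of all genes of 0.31 in place of 0.12. Fewer were higher than lower in 10 of 30 alternatives: with the stricter filter (48.2%) or none (48.4%), with the length trend removed (48.7%, or 47.8% when day 0 replicate 1 was also left out), and without day 42 replicate 1 (45.2%), day 0 replicate 1 (48.8%) or 3 (47.4%), day 14 replicate 2 (47.5%) or 3 (47.6%) or day 28 replicate 3 (47.7%). Of genes changed at least 2-fold, 67.9% were higher, and 56.9% to 84.2% over the alternatives.

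Days 28 and 42 shared 2327 genes changed in the same direction against day 0, 1471 higher and 856 lower. Independent lists of these sizes would share 994, 525 higher and 470 lower. In 20 simulations with no change and a day 0 group used by both comparisons, no gene was shared (0 at most). Few genes pass at all without change, so this 0 does not measure what shared day 0 samples add to the overlap. Across genes the fold changes correlated at 0.68, against 0.49 in the simulations, and their covariance was 0.94 against 0.05. The 3 day 0 samples are too few to be divided into sets of at least 2, so part of the excess may come from them. Between comparisons with no samples in common, 1614 genes changed in the same direction at day 28 against day 14 and at day 42 against day 0, where independent lists would share 914.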

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

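The tests of the day 0 samples as a batch, of day 28 material in day 0 replicate 1 (4 forms were tried), of fragment length, and of the genes found in day 28 replicate 2 alone were chosen after the results were seen, as were the removal of the length trend and the comparison of correlations by size. Genes were picked out here because they passed against day 0 in opposite directions on different days and also differed between those days by edgeR's quasi-likelihood test. There were 10 such genes for days 7 and 14, 252 for days 7 and 28, 376 for days 7 and 42, 17 for days 10 and 14, 261 for days 10 and 28, 425 for days 10 and 42, 45 for days 14 and 28, 159 for days 14 and 42, and 179 for days 28 and 42. For days 7 and 42, 246 of the 376 were lower first and higher later. For days 7 and 10 there were 0.

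The day 0 samples stood apart from the 15 infected ones. The test assumed that a batch particular to day 0 would leave days 7 and 14 alike. The 4773 genes changed at day 10 stood 0.88 ± 0.07 (log2, SD, n = 3) from day 0 at day 7 and 0.63 ± 0.03 at day 14. This difference of 0.25 cannot decide whether a batch was the whole cause. The genes were chosen at day 10, where no gene passed against day 7 but 1502 differed from day 14. Day 7 could therefore score above day 14 whatever set day 0 apart. A length trend is not the whole cause, since 4476 genes passed at day 7 against day 0 after its removal. A batch as the whole or a part of the cause, age and infection stay open. No uninfected samples of later days are in the series, and the day 0 files are named in another style than the rest. A genetic difference of the mice stays open too. There were 4 clusters, with numbers in a span of 6, at 7.07 CPM or more in each day 0 sample and at most 0.12 in all others. Cluster 22788 showed the reverse. Outside these, 27.8% (95% exact interval 21.7 to 34.6) of 198 genes at least 4-fold from day 0 had another of the set within 5 cluster numbers, against 31.8% of as many control genes; the bound set beforehand counted this against a genetic difference, but it was wrong, since an interval that spans the control separates nothing and a few loci would not raise a share over 198 genes.

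The day 28 samples and day 0 replicate 1 held relatively more of the short transcripts, with rank correlations of each sample's deviation with length of -0.54, -0.5, -0.33 and -0.47. The length trend is not the whole of the step from day 14 to day 28, since 3199 genes passed after its removal. For the day 28 samples a shorter fragment length is not the whole cause. The 6 samples outside the pattern with mean fragments no longer than the 192 bases of day 28 replicate 3 had correlations with length of -0.05 to 0.27 (SD 0.11). Their fragments were 175 to 189 bases, none as short as the 160 of day 0 replicate 1, so the test does not decide for that sample. Whether the length trend is the whole of the likeness of day 0 replicate 1 to day 28 cannot be told apart from other causes. The deviation of day 0 replicate 1 from the other day 0 samples correlated with the step from day 14 to day 28 across genes. The correlation was 0.45 before and 0.32 after removal, against -0.25 to 0.17 (SD 0.14) after removal in 9 samples of days 7, 10 and 42. The bound set beforehand, a value above every one of these, was met and counted against the length trend. It left out the spread. A margin of the SD was added after the values were seen, and 0.32 did not exceed the largest size, 0.25, by that much. Day 28 material in day 0 replicate 1 cannot be told apart from other causes either. Cluster 22788, with 0 counts there, allows a share of at most 0.67%, and 456 genes higher at day 28 would need a median of 4.27%. With quartiles of -0.00362% and 11.2% the 456 genes set no bound. The limit of 0.67% is that of 1 of 13 genes near absent from the other day 0 samples and present in each day 28 sample. Of the 13, 5 lay under 2% of their lowest day 28 level and 7 above 50%, which a single share alone does not give. Of the other forms 1 was undecided, with 6 of 17 genes near absent from the other day 0 samples under 0.02 of their median day 28 level and 8 above 0.5, and 2 argued against a mixture but were not relied on: 32 and 9 of 44 genes with the mean level, which lets in genes of day 28 replicate 2 alone, and a correlation of 0.43 after taking out 0.67%, which so small a share could hardly move; fragment length as part of the cause stays open, since within days it went with the correlation with length (r = 0.68 over 18 samples, 0.65 without day 0 replicate 1, which had 160 bases), as do RNA quality, library preparation and the day of infection itself, which were not tested.

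In day 28 replicate 2, 9 genes were found at 2.22 to 48.1 CPM that lay at or under 0.1 CPM in every other sample. RNA of another tissue or of an outside sample remains a candidate explanation that cannot be told apart from a state of that sample, since the 9 genes could not be named. Each of the other 17 samples had 0 such genes.

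Other divisions of the samples were tried for each count. For the time course, 1 of 100 assignments of the 18 samples to days, the real one, gave as many genes (10857), and the highest other gave 478. A share of 1 in 100 is the smallest that so many assignments can give. It shows that samples of a day resembled each other more than samples grouped at random. With 3 samples against 3, the 10 possible divisions are too few for a share under 0.05. In 8 comparisons 1 of the 10, the real one, gave as many genes. The real and the highest other counts were 3941 and 1 (day 7 against 0), 4773 and 0 (day 10 against 0), 2264 and 1 (day 14 against 0), 6014 and 32 (day 42 against 0), 1502 and 0 (day 14 against 10), 4177 and 0 (day 28 against 14) and 6546 and 0 (day 42 against 28). At day 10 against day 7 all 10 divisions gave 0. At day 28 against day 0 the real count was 4557, and the division that put day 0 replicate 1 with day 28 replicates 1 and 2 gave 1651.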

How the results depend on the processing

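The alternatives on transcript length and without day 28 were chosen after the data were seen. Requiring at least 2-fold lowered the counts to 1408, 1830, 970, 2077 and 2740 for days 7, 10, 14, 28 and 42 against day 0, to 541, 1546 and 2455 for day 14 against 10, 28 against 14 and 42 against 28, to 6196 for the time course and to 1238 for the overlap of days 28 and 42, by construction. Otherwise counts moved by over 1.5 times in 4 cases besides single samples: DESeq2 called 13 genes at day 10 against 7, the compared libraries alone gave 3879 at day 42 against 0 (fewer samples estimate the spread), and day 14 against 10 rose to 2298 with the length trend removed and 2485 when day 0 replicate 1 was also left out, where the cause was not tested. Day 7 as the reference gave 5576 and 7115 genes for days 28 and 42, of which 2529 and 4085 were shared in direction with the lists against day 0. Of 617 values of single genes under the alternatives, 606 kept direction and call. The exceptions were the gene with the largest share at day 0, at -1.56 (adjusted p = 0.12) at day 42 with the compared libraries alone, the leading gene at day 14, never past the threshold, which ran from -0.55 without day 0 replicate 1 to 0.15 without day 0 replicate 2, the fifth gene at day 10 and the tenth at days 7 and 14, whose calls were lost in 1, 2 and 4 omissions of single samples, and the tenth gene at day 42, at 0.95 (adjusted p = 0.047) without day 42 replicate 1 and -0.07 without day 42 replicate 2.

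With each sample left out in turn, the counts ran from 2537 (without day 7 replicate 3) to 4370 for day 7 against 0, 3638 to 5350 for day 10 against 0, 1321 (without day 14 replicate 2, and 1401 without replicate 1) to 2726 for day 14 against 0, 3128 to 5811 for day 28 against 0 and 5024 to 6168 for day 42 against 0. They ran from 0 to 1 for day 10 against 7, 946 (without day 10 replicate 2, and 964 without day 14 replicate 3) to 2115 for day 14 against 10, 2206 (without day 28 replicate 1, and 2229 without day 14 replicate 2) to 4941 for day 28 against 14, 4384 to 7018 for day 42 against 28, and 10097 to 11322 for the time course. With each of the 9 samples of days 0, 28 and 42 left out, the overlap ran from 1864 to 2566. At 3 samples a day, changes under 2-fold were mostly missed in simulated data.

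The replicate numbers did not pair the samples: deviations of equal-numbered samples correlated between -0.29 and 0.32 (median 0), 5 of 45 pairs exceeded 0.1, and 6 of 18 samples correlated best with their own number. With the replicate block the counts were 3932, 4750, 2263, 4544 and 6039 against day 0, 0, 1476, 4235 and 6518 for consecutive days and 10748 for the time course, none moved by over 1.5 times. The tests of gene lists and their alternatives were not run, because the files do not pair clusters with names.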

Other observations

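The abundant genes were chosen after their values were seen, and some followed courses not described so far. The fifth gene by largest share held 0.29% ± 0.07 of the counts at day 0 (SD, n = 3), 0.841% ± 0.16 at day 28 and 2.45% ± 1.3 at day 42, a log2 fold change of 2.99 (SE 0.46, adjusted p = 7e-05 by edgeR). It also passed at day 10, at 0.691% ± 0.55 (log2 fold change 1.55, adjusted p = 0.012), but without day 10 replicate 2 the share was 0.375%, the fold change 0.67 and the adjusted p 0.15 (range 0.0042 to 0.15 over its alternatives). The tenth rose from 0.38% ± 0.085 at day 0 to 0.926% ± 0.33 at day 7 (adjusted p = 0.016), 1.07% ± 0.22 at day 10 (0.0075), 1.1% ± 0.21 at day 14 (0.022) and 1.61% ± 0.65 at day 28 (0.0024). The day 7 call was lost without day 0 replicate 2 (adjusted p = 0.06) or day 7 replicate 3 (0.076), with a range of 0.0012 to 0.076 over its alternatives. The day 14 call was lost without day 0 replicate 2 (0.072) or 3 (0.059) or day 14 replicate 1 (0.076) or 2 (0.05), with a range of 0.0015 to 0.076. The gene stood at 0.609% ± 0.43 at day 42 (adjusted p = 0.32, or 0.047 without day 42 replicate 1, with a range of 0.047 to 0.91 over its alternatives). Without day 42 replicate 2 its share was 0.398% and its log2 fold change of 0.58 was -0.07. The 3 day 42 samples differed widely: the gene with the largest share at day 0 held 0.785%, 6.03% and 3.35% of the counts in replicates 1, 2 and 3, and the seventh gene 3.26%, 0.88% and 2.2%.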
